A study of Caenorhabditis elegans with 2 samples.

How the data were processed

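The samples were 2 biological replicates of whole C. elegans young adults of a strain with TY1::EGFP::3xFLAG inserted into mcd-1, immunoprecipitated with an anti-GFP antibody after sonication to a stated size range of 200 to 800, per the labels. They form 1 group. The labels name a possible control experiment, which was not used here, so no background measured the same way stands beside the peaks. The aligner, the peak caller and their settings are not given in the sources used here. The build is ce11, per the labels.

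The authors deposited 8 peak lists: a conservative list and a pooled list for the series, 1 list for each replicate, and a longer ranked list behind each of these. The lists of the series derive from the alignments of both replicates and those of a replicate from its own alignment, per the deposited description of the files. The deposited signal value of a peak is the peak caller's own measure of enrichment, with its scaling not given in the sources used here, and was used to rank and describe peaks. The deposited score is a whole number up to 1000 that follows the global irreproducible discovery rate (IDR). This is the expected share of irreproducible peaks among those of that rank or stronger. All 55700 ranked peaks behind the conservative list had a score within 1 of 125 times the −log2 IDR or at the maximum. The deposited −log10 IDR of the ranked lists is capped at 5. Every thresholded list was limited by the authors to an IDR of 0.01, a score of 830 or more. The deposited summit offset gave the position of the summit in a peak. The ranked lists of the series also hold 4 columns of signal per sample that carry no sample name, and these were not used. The −log10 q values that the authors deposited were not used either.

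The sequencing depth per sample is unknown, since the files hold no read counts, and no interval for a single peak was formed. The error of a peak's signal was taken from the 2 replicates. For each conservative peak, each replicate's value was that of the overlapping peak with the nearest summit in the replicate's own ranked list, divided by the median over the conservative peaks (87.3 in replicate 1 and 66.7 in replicate 2). Values are given as mean ± SD of the 2 multiples.

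The conservative list was the main set. Of its peaks 100 had a signal value under 20, and each of these lay within 1000 bp of a peak with over 2 times its signal. The central part of an autosome was the middle of 3 equal lengths. The genome sequence was RefSeq's WBcel235, the assembly of ce11, and the gene models came from Ensembl release 115. All 219336 nuclear peaks of the 8 lists ended inside these chromosomes. Genes on the 6 nuclear chromosomes were used, 19973 of them protein-coding, and the 5′ end of a gene was the outermost start of its annotation. A summit was assigned to every protein-coding gene whose window, from 1000 bp upstream to 200 bp downstream of the 5′ end, held it. Other summits were classed as exonic, intronic, within 500 bp downstream, or intergenic, in that order.

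Peak positions were compared with 1000 circular shifts, in which all summits of a chromosome moved together by a random distance of at least 10000 bp (seed 1). Their two-sided permutation p cannot go below 0.002. Gene lists and chromosomes were compared by two-sided Fisher's exact tests over genes, with odds ratios and 95% intervals formed after adding 0.5 to each cell. The p-values of the 40 lists were adjusted by the Benjamini-Hochberg method. Genes that share a promoter or lie side by side are not independent, so the gene lists, but not the chromosomes, were also compared with the shifts. For noncoding genes, summits within 200 bp of the gene were counted and compared with the shifts. Folds over shifted counts of genes have 0.5 added to both counts. For motifs, 101 bp windows at 2102 promoter-proximal summits were matched 1 to 1 with windows of genes without a peak in any thresholded list, at the same distance from the 5′ end and within bins of 2 percentage points of GC content. A match was found for 2072 windows, with a mean GC content of 47.4% in both sets. The presence of 22 motifs from the literature and of 2080 strand-collapsed 6-mers was tested by Fisher's exact test with Benjamini-Hochberg adjustment. Overlaps were counted with bedtools 2.31.1, and all else with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1; plots used matplotlib 3.10.9.

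The tests, gene lists, motifs, alternatives and the rule for named genes were fixed before the data were examined. The rule named mcd-1, every symbol-bearing gene of the 25 strongest conservative peaks that are promoter-proximal to at least 1 gene with a symbol, up to 4 members with the strongest peak of each list past the threshold, every member with a peak of the DRM complex and synMuv B list and of the apoptosis and engulfment list, and the 5 motifs and 5 6-mers with the smallest adjusted p. The peaks away from promoters, the members without a peak and the placing of GAGCGC were chosen after their values were seen. The alternatives were the pooled list, each replicate's own list in place of the conservative list, the peaks at or above the median signal, windows of 500 or 2000 bp upstream, the nearest gene alone, a background of genes with a symbol, other overlap rules, and motif windows of 51 or 201 bp or flanking controls. Chosen after seeing the data were an IDR of 0.001 or 0.05, leaving out peaks with a signal under 20, merging overlapping peaks, leaving out chromosome V or 4 large gene families, and 8-mers.

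The steps were tested on simulated data. For the gene list enrichment, 20 of 20 planted lists of 40 genes at 4 times the odds were found over 19973 genes, with 0 of 20 unchanged lists called. For the motifs at summits, a 6-mer planted in 5% of windows came first among 2080, and 0 of 2080 were called between sets of windows without it. In the simulation hits were drawn independently for each gene, and both sets of windows were drawn alike, without the matched controls. The absence of false calls thus does not cover errors from genes that share a peak, or from differing composition of summit and control windows.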

Results

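Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans young adults, 65 hours old, of a strain in which CRISPR editing had joined a TY1, EGFP and 3xFLAG tag to the endogenous mcd-1 gene. An antibody against GFP was used to recover DNA bound by the tagged protein. MCD-1 is a zinc finger protein named as a modifier of cell death, which acts redundantly with the retinoblastoma homologue LIN-35 and its partners. The data comprised 2 biological replicates of 1 group, so they show where the protein was recovered and contain no comparison between conditions. The sequencing depth is unknown, because the peak lists hold no read counts. The authors' conservative list held 3903 peaks, with a median width of 370 bp and a coverage of 1.21% of the nuclear genome. The signal value of each peak, given by the authors, had a median of 148 and ranged from 2.02 to 6544. Coordinates refer to the ce11 build, in which positions are counted from 1.

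At the tagged locus itself a peak stood at the promoter of mcd-1 (WBGene00013096, chromosome II, 13888544 to 13898463, plus strand). It spanned 13888392 to 13888633 on chromosome II in the conservative list, with its summit at -38 bp from the annotated 5′ end, where negative values lie upstream. Its signal value of 365 placed it at rank 748 of the 3903 peaks. The peak was found in both replicates, with signals of 2.32 and 2.38 times the median conservative peak (mean 2.35 ± 0.0417 SD, n = 2). No other peak of a thresholded list lay within 2000 bp of the gene, its 3′ end included.

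The first question was whether the replicates gave the same sites. The replicates' own lists held 3339 and 3051 peaks, a self-consistency ratio of 1.09, and the pooled and conservative lists held 4460 and 3903, a rescue ratio of 1.14. Of the nuclear peaks of replicate 1, 2347 of 3339 (70.3%) overlapped a peak of replicate 2 by at least 1 bp, against 1.91% ± 0.249 (SD over 1000 circular shifts). Of the nuclear peaks of replicate 2, 2307 of 3030 (76.1%) overlapped a peak of replicate 1, against 2.08% ± 0.278 in the shifts. The two-sided permutation p was 0.002 in both directions, the smallest that 1000 shifts can give. Shifted peaks do not keep the peaks' preference for promoters, described below, so part of the excess over the shifts can come from that preference. Requiring a reciprocal overlap of 50% lowered the shares to 59.6% and 65.2%.

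Signal values were then compared over the conservative list, whose peaks the IDR threshold had selected for similar ranks in the replicates, so part of this likeness follows from the selection. Of the 3903 conservative peaks, 3860 overlapped a peak in each replicate's ranked list. Across these peaks, which are not independent replicates, the signal values had a Spearman rho of 0.823 and a Pearson r of 0.909 on the log2 scale. The SD of the log2 difference between replicates was 0.54, and 4.77% of peaks lay over 2-fold from the median ratio; over the pooled list these were 0.80 and 12.8%, with a rho of 0.760 and an r of 0.827. Signals were 1.32 times higher in replicate 1 at the median, so each replicate's values are given below as multiples of its own median over the conservative peaks, with n = 2.

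**Figure D1:**
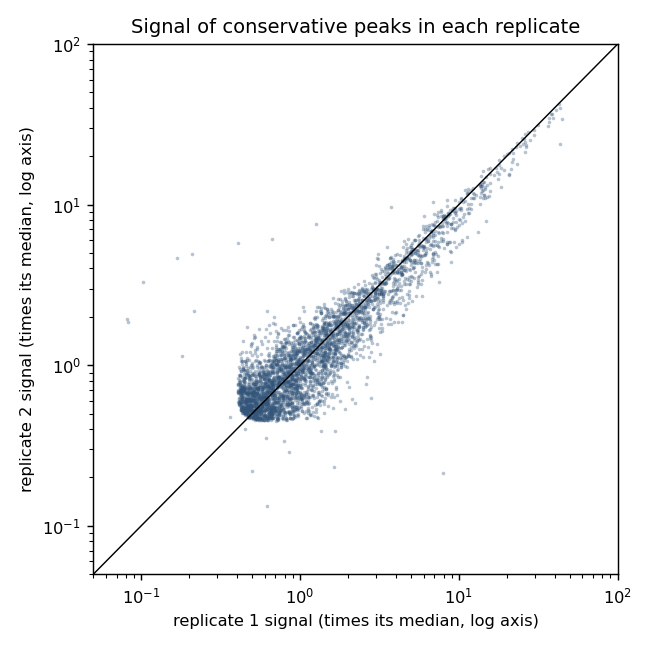
Signal of each of the 3860 conservative peaks found in both replicates, as a multiple of the replicate's own median, on log axes; each point is a peak and the line marks equal values. Points follow the line, with a Spearman rho of 0.823.

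Promoters of ribosomal protein genes were among the strongest named sites. The highest signal of all, 6544, stood at eelo-2 (chromosome IV, 17249675 to 17250153), at 42.6 ± 0.496 times the median peak. Next among promoters with a gene symbol came a peak between rpl-7A and set-21 (IV, 4390403 to 4390904) at 40 ± 1.65 times the median, and one upstream of rpl-20 (IV, 4749821 to 4750350) at 39.3 ± 7.26. A peak shared by rpl-12 and the neighbouring lin-54 (IV, 13240429 to 13240938) reached 34.8 ± 3.28 times the median. Its summit lay at -27 bp from the 5′ end of rpl-12 and at -366 bp from that of lin-54, which encodes a DNA-binding subunit of the DRM complex. The exonic summit of ints-4, a subunit of the Integrator complex, gave 35.8 ± 1.41 times the median (I, 13663113 to 13663675). The AAA ATPase gene cdc-48.1 (II, 10563341 to 10563800) gave 33.6 ± 14.1, with the replicates at 43.6 and 23.7.

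The remaining strongest promoters of genes with a symbol gave from 17.9 ± 3.72 times the median, at the importin gene imb-3, to 33.5 ± 3.83, at the CCR4-NOT subunit gene ntl-11. They included ska-3 with rps-12 (29.4 ± 0.153), iff-2, which encodes translation factor eIF5A (27.7 ± 0.904), gpap-1 with scpr-1 (26.7 ± 1.00), and the replication protein gene rpa-2 (25.6 ± 0.229). Ribosomal protein genes rpl-3 (25.5 ± 0.643), rps-15 (24.6 ± 1.24) and rps-20, which shares its peak with ekl-4 (20.5 ± 3.90), were also among the 25. So were vps-39 (25.3 ± 1.26), mtcu-2 (24.7 ± 2.75), the chaperonin gene cct-1 with mig-5 (23.6 ± 3.28), tasp-1 (23.8 ± 0.661), and the ATP synthase gene atp-1 with mcrs-1 (23.7 ± 0.660). The E2F gene efl-1, within the same peak as the window of fbxa-90, gave 22.8 ± 0.0942. The list closed with ndk-1 (21.8 ± 0.551), puf-9 (20.8 ± 0.349), the mitochondrial ribosomal gene mrps-7 (20 ± 2.44) and dnj-13 (19.7 ± 0.544). The SD of these values comes from 2 replicates.

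Where the peaks lay relative to genes was asked next. Promoter-proximal summits, within 1000 bp upstream to 200 bp downstream of the 5′ end of a protein-coding gene, made up 2102 of the 3903 peaks (53.9%). Circularly shifted peaks gave 21.4% ± 0.697 (SD over 1000 shifts), a 2.52-fold difference. Exonic summits made up 7.66% against 23.2%, intronic summits 19.4% against 31.5% and intergenic summits 14.6% against 20.5%. Summits within 500 bp downstream of a gene were at 4.43% against 3.38%. Each class differed from the shifted peaks with a permutation p of 0.002, the smallest possible. Among promoter-proximal summits 89.5% lay upstream of the nearest 5′ end, with a median position of -186 bp, and 637 of the 2102 (30.3%) lay in the windows of genes on both strands. Since the window reaches 1000 bp upstream but 200 bp downstream, most summits spread evenly over it would also lie upstream.

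The promoter share rose with signal. With the peaks ordered by signal into 4 groups, 75% of summits were promoter-proximal in the strongest group, and in the following groups 58.4%, 45.1% and 37.0%. Several of the strongest peaks nevertheless lay away from promoters. The peak of rank 2 (IV, 4725354 to 4725863, signal 6369) and that of rank 5 (IV, 4727812 to 4728299, signal 5821) lay near K08F11.1, at the position of a noncoding RNA gene and of a pseudogene respectively. The peak of rank 6 lay downstream of a gene on chromosome I (2639558 to 2640058), and that of rank 7 in an exon of C34C12.2 on chromosome III (3456200 to 3456659). A peak of rank 21 lay in an intron of scc-2 (II, 255113 to 255583), which encodes a cohesin loader.

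**Figure D2:**
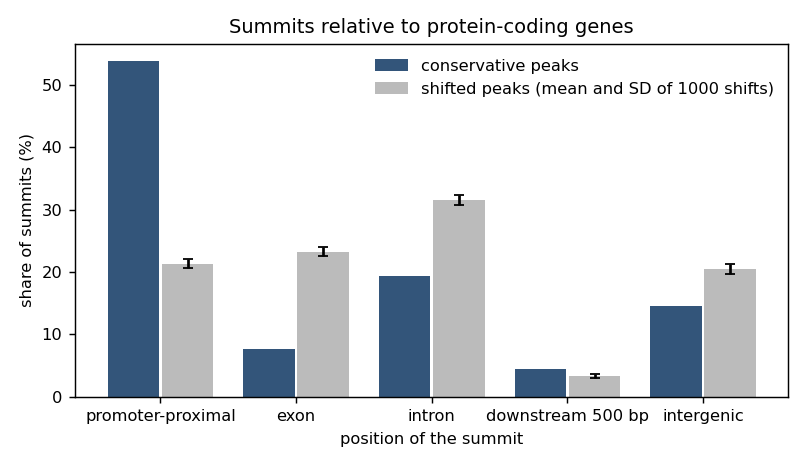
Share of conservative summits in each position class beside the mean of 1000 circular shifts, with bars for the SD of the shifts. Promoter-proximal summits stand at 53.9% against 21.4%.

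The X chromosome and the autosomes were compared because germline activity differs between them in C. elegans. A promoter-proximal summit was found at 206 of 2731 genes on X (7.54%) and at 2430 of 17242 autosomal genes (14.1%). The odds ratio was 0.498 (95% interval 0.430 to 0.578, two-sided Fisher p = 1.98e-23, with genes not being independent replicates). Among autosomes, chromosomes I and III had the highest shares, 20.5% and 20.6%, chromosomes II and IV had 13.1% each, and chromosome V had 8.29%. The central and the outer parts of the autosomes did not differ detectably, at 13.9% and 14.2% of genes (odds ratio 0.972, 95% interval 0.890 to 1.06, Fisher p = 0.543).

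**Figure D3:**
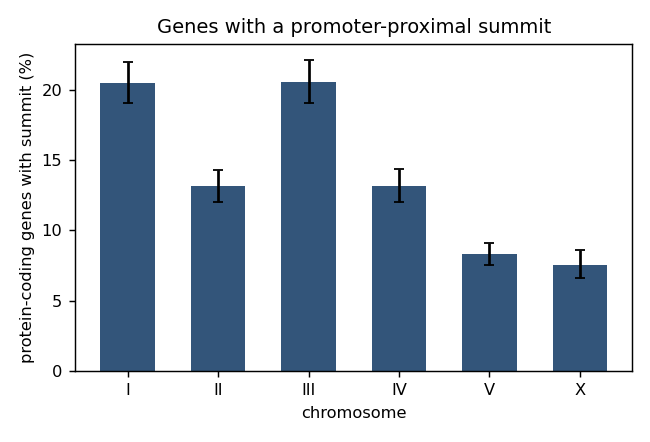
Share of protein-coding genes on each chromosome with a promoter-proximal conservative summit; bars are Wilson 95% intervals, which cover counting error only. X stands at 7.54% and chromosome III at 20.6%.

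Which groups of genes carried these summits was the main question that the design allows. Of 19973 protein-coding genes, 2636 (13.2%) had a promoter-proximal conservative summit. Genes of translation, cell division, RNA processing and protein turnover were far above this share, while chemoreceptors, channels, neuropeptides and other large families of specialised genes were below it. Of the 40 gene lists, 21 were above the other genes and 12 below at a Benjamini-Hochberg adjusted Fisher p of 0.05, and 7 were neither. A summit counted for every gene whose window held it, so a single peak can stand for members of different lists. For many members named below another gene had its 5′ end nearer to the summit. Among these were rpl-20, rps-12, zwl-1, prp-19, cct-1, hsp-110, cct-8, tbb-1, klp-18, dnc-2, col-71, col-2 and col-38.

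Cytosolic ribosomal proteins led, with 70 of 83 genes (84.3%, odds ratio 35.3, 95% interval 19.7 to 63.2, adjusted Fisher p = 2.2e-47), and 43 of 83 (odds ratio 9.91) when each summit was given to the nearest gene. Among them were rpl-7A, rpl-20, rpl-12 and rps-12, with the signals given above. Among the other lists of translation, translation factors had 26 of 41 (odds ratio 11.3, and 7.18 with the nearest gene alone), among them iff-2, eef-1G (12.4 ± 1.77 times the median peak, in a peak shared with ctf-4), eif-3.C (8.81 ± 0.0569) and the elongation factor gene eef-2 (4.65 ± 0.790). Mitochondrial ribosomal proteins had 33 of 70 (odds ratio 5.94), led by mrps-7, mrpl-28 (17.6 ± 1.18), mrpl-45 and mrpl-55. Aminoacyl-tRNA synthetases had 12 of 31 (odds ratio 4.23), with vars-1, ears-2, mars-1 and pars-2 between 2.73 and 3.86 times the median. The synthetase call was not kept on replicate 1's own list, where the odds ratio was 2.56 and the adjusted Fisher p 0.0583.

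Genes of the cell cycle formed the second large group. DNA replication and S phase had 31 of 45 genes (68.9%, odds ratio 14.4, 95% interval 7.74 to 26.9, adjusted Fisher p = 1.17e-16). Its strongest members were rpa-2, ctf-4 (12.4 ± 1.77), the helicase subunit gene mcm-2 (12 ± 0.476; II, 12006691 to 12007062) and pcn-1, which encodes the sliding clamp PCNA (9.26 ± 0.312; IV, 4049505 to 4049914). Mitosis and spindle had 43 of 63 genes (68.3%, odds ratio 14.2, 95% interval 8.37 to 24.0, adjusted Fisher p = 1.34e-22), with zwl-1 (11.5 ± 0.673), the securin gene ify-1 (11.0 ± 1.21), knl-3 (8.04 ± 0.199) and hcp-1 (6.95 ± 1.05) strongest. With the nearest gene alone the odds ratios were 9.55 for replication and 7.35 for mitosis. Tubulins and motors had 13 of 36 (odds ratio 3.79), among them tbb-1, tba-2, klp-18 and dnc-2. Histone genes had 21 of 81 (odds ratio 2.35), with his-37 (5.20 ± 0.375) strongest, then his-67, his-68 and his-47; this difference was lost on each replicate's own list (odds ratios 1.52 and 1.48) and among peaks at or above the median signal (1.02). Meiosis genes, 11 of 46, did not pass (odds ratio 2.13, adjusted Fisher p = 0.0538), but did pass on the pooled list and on each replicate's own list.

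The DRM complex and synMuv B list holds lin-35, genes of its partners and other synMuv B genes. Of its 16 members, 10 had a summit (62.5%, odds ratio 10.7, 95% interval 4 to 28.4, adjusted Fisher p = 1.18e-05). Besides lin-54 and efl-1 these were the retinoblastoma gene lin-35 (8.71 ± 1.80; I, 5807223 to 5807713), lin-9 (8.53 ± 1.11; III, 8904097 to 8904465), lin-53 (8.34 ± 0.397; I, 9619829 to 9620176), lin-13 (2.19 ± 0.153), lin-61 (1.70 ± 0.266), lin-36 (1.33 ± 0.135), lin-15B (0.822 ± 0.0787) and lin-52 (0.577 ± 0.0937). For lin-54, lin-53, lin-61 and lin-52 another gene had its 5′ end nearer to the summit, so 6 of 16 remained when each summit was given to the nearest gene (odds ratio 5.61). The 6 members without a summit were dpl-1, hpl-2, lin-37, lin-65, met-2 and tam-1.

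Genes of apoptosis and engulfment had 9 of 37 members with a summit, and the list did not pass (odds ratio 2.2, 95% interval 1.05 to 4.58, adjusted Fisher p = 0.0603). The 9 were icd-2 (12.9 ± 1.40; I, 535224 to 535654) and icd-1 (4.98 ± 0.0740; II, 6588875 to 6589241), which encode subunits of the nascent polypeptide-associated complex, mcd-1 itself, crn-1 (1.99 ± 0.206), abl-1 (1.54 ± 0.265), ced-5 (1.33 ± 0.0998), psr-1 (0.675 ± 0.0949), crn-2 (0.659 ± 0.0132) and wah-1 (0.610 ± 0.0394). No conservative promoter-proximal summit was found at egl-1, ced-3, ced-4 or ced-9, the core cell death pathway. With each summit given to the nearest gene, or with the wider window of 2000 bp, the list passed. It also passed against shifted peaks, but those do not keep the peaks' preference for promoters. That pass is therefore no support for the list.

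RNA processing and nuclear genes were also above background. Splicing and snRNP proteins had 31 of 50 (odds ratio 10.7, and 5.19 with the nearest gene alone), led by prp-19 (16.3 ± 0.886), mog-4, snr-1 and snr-4. Nucleoporins had 15 of 26 (odds ratio 8.91, and 5.78 with the nearest gene alone; npp-12, npp-3, npp-10 and npp-8 strongest). RNA polymerases and TFIID had 18 of 40 (odds ratio 5.44; rpb-11, taf-6.2, taf-11.3 and taf-4), with an odds ratio of 2.48 on replicate 2's own list (adjusted Fisher p = 0.0483), and Mediator had 10 of 28 (odds ratio 3.74; mdt-19, mdt-9, mdt-26 and sur-2). Chromatin regulators had 31 of 63 (odds ratio 6.44), with the methyltransferase genes set-16 (12 ± 0.347) and mes-2 (10.2 ± 2.00), swsn-3 and pcaf-1 strongest. Germ granules and germline RNA regulation had 27 of 71 (odds ratio 4.10), with mut-15 (13.7 ± 0.292), mex-1, pos-1 and hrde-1.

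Lists of protein turnover, energy metabolism and small GTPases were higher too. Heat shock and proteostasis had 24 of 40 (odds ratio 9.84, and 4.46 with the nearest gene alone), led by cct-1, dnj-13, hsp-110 (15.6 ± 3.90) and cct-8. The proteasome had 18 of 33 (odds ratio 7.90; rpn-3, rpt-2, rpn-9 and rpn-11) and the vacuolar ATPase 12 of 20 (odds ratio 9.71; vha-8, vha-1, vha-18 and vha-13), whose odds ratio was 4.81 on replicate 1's own list. The peak of rpn-3 is also that of hsp-110, and the peak of vha-18 is also that of pos-1. The respiratory chain and ATP synthase had 38 of 70 (odds ratio 7.89; atp-1, ucr-2.1, nduc-2 and cox-5A). Small GTPases had 13 of 42 (odds ratio 3.02; rab-18, rab-7, rab-1 and sar-1), a difference lost when summits counted for the nearest gene (odds ratio 1.61, adjusted Fisher p = 0.339). Here rab-7 shares its peak with mex-1. Ubiquitin conjugation had 16 of 60 (odds ratio 2.45; ubc-6, uev-1, cul-4 and ubc-9), a difference lost on replicate 2's own list (odds ratio 1.91, adjusted Fisher p = 0.110) and against genes with a symbol (1.86, adjusted Fisher p = 0.0650).

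Chemoreceptor genes had 14 of 1309 (1.07%, odds ratio 0.0685, 95% interval 0.0407 to 0.115, adjusted Fisher p = 1.10e-60), the strongest being sri-5, srh-16, sre-23 and srh-269. Potassium and acetylcholine channels had 0 of 138 (odds ratio 0.0236, and 0.0765 on replicate 1's own list) and neuropeptides 2 of 140 (0.118; ins-39 and nlp-4). F-box families had 9 of 322 (0.196; fbxa-90, fbxb-85, fbxa-83 and fbxc-33), C-type lectins 9 of 240 (0.267, and 0.155 on replicate 2's own list; clec-104, clec-126, clec-57 and clec-87) and collagens 7 of 170 (0.300; col-71, col-2, col-38 and col-63). Nuclear hormone receptors had 16 of 269 (0.424, and 0.283 on replicate 1's own list; nhr-47, nhr-142, nhr-255 and nhr-48), cytochrome P450s 2 of 74 (0.226, and 0.345 on replicate 1's own list; cyp-25A4 and cyp-31A3) and UDP-glucuronosyl transferases 1 of 67 (0.148, and 0.0667 with the nearest gene alone; ugt-12). Homeobox genes had 5 of 94 (0.403; ceh-39, ceh-38, ceh-92 and ceh-99), hypodermis and cuticle genes 1 of 47 (0.212; wrt-1) and major sperm proteins 0 of 31 (0.104).

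These 12 lists were below the other genes, but against shifted peaks the test was passed by 2 of them, chemoreceptors and channels. For homeobox genes the difference was also lost on each replicate's own list (adjusted Fisher p = 0.0984 and 0.112), and for hypodermis genes and major sperm proteins on replicate 2's list (adjusted Fisher p = 0.0739 and 0.0581). For cytochrome P450s it was lost among peaks at or above the median signal (odds ratio 0.347, adjusted Fisher p = 0.0801). Homeobox genes and major sperm proteins lost it there too, and at an IDR of 0.001. Hypodermis genes and major sperm proteins also lost it with a window of 500 bp upstream and with the nearest gene alone. Lists of developmental timing and vulval fate (7 of 37), body wall muscle (5 of 42), intestine (5 of 56), neurons (5 of 64) and sperm (3 of 46) did not differ detectably from the other genes. Of these, developmental timing and vulval fate passed against shifted peaks (7 genes against 1.73 ± 1.26, adjusted permutation p = 0.00959). Shifted peaks do not keep the peaks' preference for promoters, so a list at the share of all genes also exceeds them. Body wall muscle, at 11.9%, had 5 genes against 1.76 ± 1.32. The pass against shifts is therefore no support for the developmental timing list. Intestine passed as a list below the other genes among peaks at or above the median signal.

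**Figure D4:**
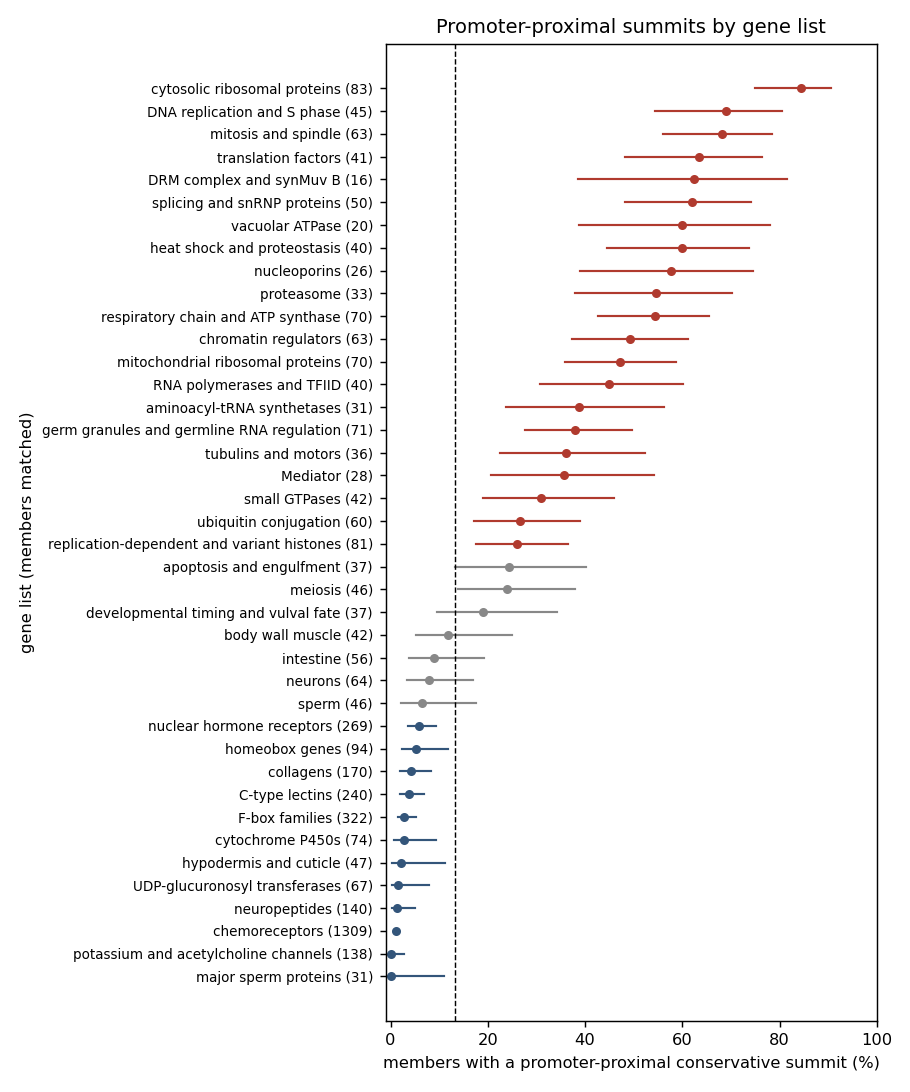
Share of each list's members with a promoter-proximal conservative summit, with Wilson 95% intervals, which cover counting error only; the dashed line is the share of all protein-coding genes, 13.2%. Red lists are above and blue lists below the other genes at an adjusted Fisher p of 0.05, and grey lists are neither; cytosolic ribosomal proteins stand at 84.3% and chemoreceptors at 1.07%.

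Several classes of noncoding genes also had summits more often than shifted peaks. No control immunoprecipitation was used, so recovery of highly transcribed genes cannot be told apart from binding in any class. Whether promoters of protein-coding genes nearby account for these summits was examined for tRNA genes alone. A summit lay within 200 bp of 251 of 612 tRNA genes (41%), against 9.80 ± 3.28 genes in shifted peaks. This is 24.4-fold, where each fold for noncoding genes has 0.5 added to the observed and to the shifted count, which lowers it most in the smallest classes. Spliceosomal and other snRNA genes had 33 of 99 against 2 ± 1.38 (13.4-fold), SL RNA genes, which provide the spliced leader of trans-splicing, 12 of 30 against 0.563 ± 0.778 (11.8-fold) and snoRNA genes 90 of 346 against 7.52 ± 2.81 (11.3-fold). Other noncoding RNA genes had 701 of 8058 (4.29-fold) and miRNA genes 12 of 261 (2.46-fold, and 3.79-fold on replicate 2's own list). The 21U RNA genes, by contrast, had 34 of 15363 against 237 ± 50 in shifted peaks, and pseudogenes 56 of 2128 against 126 ± 10.9. No rRNA gene of 20 had a conservative summit, with 0.652 in shifted peaks, but the ranked list holds 2 peaks past the IDR threshold at genes named rrn-4.2 (signals 165 and 78.6) that the conservative list leaves out. Apart from rRNA, each class passed with an adjusted permutation p of at most 0.0135.

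Short sequences at promoter-proximal summits were compared with promoter windows that had no peak in any thresholded list, matched in GC content and in distance to the 5′ end. The 6-mer GAGCGC stood in 468 of 2072 windows reaching 50 bp to each side of the summit (22.6%) and in 58 of 2072 control windows (2.80%), an odds ratio of 10.1 (95% interval 7.60 to 13.3, adjusted Fisher p = 1.87e-87). The next 6-mers by adjusted p were AGCGCG (18% against 3.28%), ACGCGC (17.9% against 3.91%), AACGCG (15.7% against 3.72%) and CGCTCC (16.7% against 4.30%). Overlapping 6-mers can come from the same site. The sequence GGAGCGCG holds GAGCGC, AGCGCG and, on the other strand, CGCTCC, while AAACGCGC holds ACGCGC and AACGCG. Differences of such 6-mers are not independent. In all, 308 6-mers were more frequent at summits and 462 less frequent. The control windows were matched in GC content but not in dinucleotides. Shuffles of the 2072 summit windows that keep their dinucleotides gave GAGCGC in a mean of 146 windows, more than the 58 control windows. Part of these differences can therefore come from dinucleotide composition, and the other 6-mers were not set beside shuffles.

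Of the 22 motifs taken from the literature, 7 were more frequent and 7 less frequent at summits; on the replicates' own lists 3 and 4 were less frequent. The E2F core TTSSCGC led, in 17% of summit windows against 6.03% (odds ratio 3.18, 95% interval 2.57 to 3.94, adjusted Fisher p = 9.18e-28). The extended LIN-54 site TTYRAA followed with 32.8% against 18.3% (odds ratio 2.18). Then came the cell cycle homology region TTYGAA with 25.9% against 14.8% (2.01), a difference lost in windows of 51 bp (1.18, adjusted Fisher p = 0.296). Each TTYGAA site is also a TTYRAA site. The 536 summit windows with TTYGAA are thus among the 680 with TTYRAA, and these differences are not independent. The motif CTGCGTCT, known from regions bound by many factors, stood in 8.59% against 3.14% (2.89), and GAGAGAG in 9.03% against 4.87% (1.93). Against windows 500 bp from the same summits, which had a lower GC content of 36.8% against 47.7%, the TTYRAA and TTYGAA differences turned round, with odds ratios of 0.716 and 0.814.

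The placing of GAGCGC and its link to signal were measured after it had been found. Of 586 occurrences within 100 bp of these summits, 299 (51%) lay within 20 bp, where an even spread would give 20%. GAGCGC stood in 46.3% of windows in the strongest of 4 groups by signal (Wilson 95% interval 42.1 to 50.6), and in 20.5%, 15.4% and 8.11% in the following groups.

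**Figure D5:**
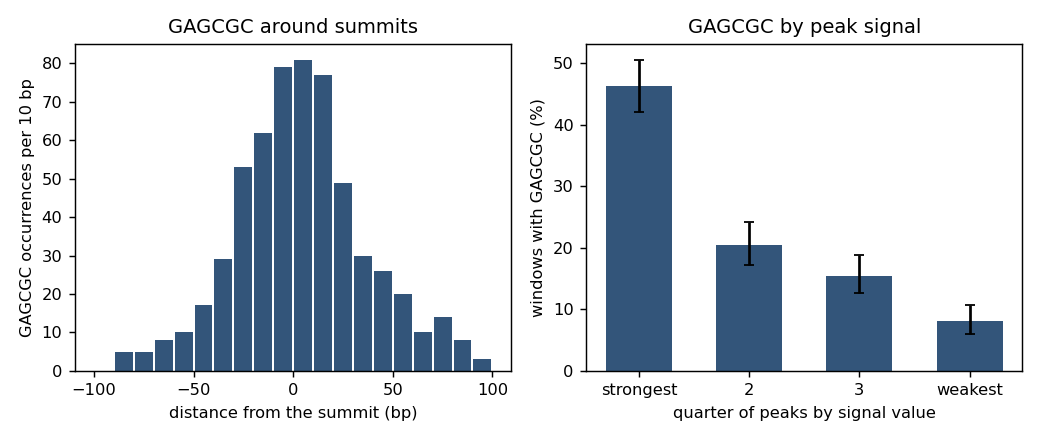
Left, occurrences of GAGCGC on either strand in 10 bp bins around promoter-proximal summits; right, share of summit windows with GAGCGC in 4 groups by signal value, with Wilson 95% intervals. The share is 46.3% in the strongest group and 8.11% in the weakest.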

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

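The mitochondrial peaks and the peaks missing from the conservative list below were signals in data that the comparisons did not use. The tests of shared promoters and the shuffles of ribosomal protein and tRNA windows were chosen only after the result was seen.

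Replicate 2's own list held 21 peaks on the mitochondrial genome, with signal values up to 1756, while replicate 1's own list and the conservative list held 0. The ranked list behind the conservative list held 41 nuclear peaks past the threshold that the conservative list does not hold, the strongest with a signal value of 1839 (X, 15810969 to 15811220).

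Peaks at ribosomal protein promoters were the most frequent of any gene list. That they belong to the other gene of a shared promoter as a whole is argued against by the odds ratio of 9.91 that remained with each summit given to the nearest gene. Recovery of highly transcribed promoters with no sequence preference stays open. GAGCGC stood in 15.9% of their 69 summit windows, above the 2.80% of control windows (Fisher p = 7.18e-06), which meets the bound set beforehand for excluding it. That bound was wrong, because the controls did not share the composition of this group: shuffles of the same windows that keep their dinucleotides gave a mean of 6.25 and up to 15 windows, against the 11 observed. The 69 windows, 58 of them without GAGCGC, cannot be told apart from such recovery without a control immunoprecipitation, which was not used here, and no biological explanation was tested.

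Peaks at tRNA genes numbered 227. That they come from promoters of protein-coding genes nearby is argued against by 203 tRNA genes that had a summit outside every promoter window, against 4.72 ± 2.28 in shifted peaks (permutation p = 0.002, the smallest possible). Recovery of highly transcribed genes with no sequence preference cannot be told apart from binding: GAGCGC stood in 18 summit windows (7.93%) and in 1.39% of windows 500 bp away, which meets the bound set beforehand. That bound was wrong too, because the flanking windows had 36.4% GC against 51.7%, and dinucleotide shuffles of the summit windows gave up to 21. Their median signal value, 153, was close to the 148 of the other peaks, and no biological explanation was tested.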

How the results depend on the processing

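The tests with an IDR of 0.001 or 0.05, without peaks of signal under 20, with merged peaks, without chromosome V, without 4 gene families and with 8-mers were chosen only after the result was seen. Across settings, promoter-proximal summits stayed above the shifted peaks (1.81-fold to 3.42-fold), genes on X stayed below autosomal genes (odds ratio 0.415 to 0.521), and 6 noncoding classes stayed above. Using ranked lists at an IDR of 0.01, 0.001 or 0.05 gave self-consistency ratios of 1.04 to 1.16 and rescue ratios of 1.09 to 1.2. The overlap of replicate 1 with replicate 2 and of replicate 2 with replicate 1 was 59.6% and 65.2% with a reciprocal overlap of 50%, 66% and 72.8% with summits within 100 bp, and 79.3% and 87.5% among peaks at or above the median signal of each list. The rho between replicates was 0.760 over the pooled list, which holds weaker peaks. The odds ratio of central against outer parts of autosomes, not past the threshold in any setting, was 1.01 without replicate 2 and 0.971 without replicate 1, and 1.001 among peaks at or above the median signal; the cause was not tested. Between 20 and 24 lists were above background in every setting. Between 9 and 12 were below, except with circular shifts, where 2 were below. Shifted summits were promoter-proximal less often than the peaks (21.4% against 53.9%), so a list can exceed them without a preference for its genes. Against the shifts nuclear hormone receptors stood at 1.61 times and homeobox genes at 1.15 times the shifted peaks, with 0.5 added to both counts. Windows of 51 bp gave 190 6-mers and 4 motifs above controls, and windows 500 bp away gave 572 6-mers, with TTYRAA at 0.716 and TTYGAA at 0.814, where the controls had less GC. GAGCGC had odds ratios of 5.96 to 16.8. With 2 replicates and no read counts, the depth behind weak peaks is unknown.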

Other observations

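The tests of signal by GAGCGC, of 8-mers and of shuffles by gene group or away from promoters were chosen only after the result was seen, and every test of GAGCGC here followed its finding at promoter-proximal summits.

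Longer sequences were also more frequent at the promoter-proximal summits, some of which hold GAGCGC on either strand. Of the 8-mers, GCGCTCCA stood in 187 of 2072 summit windows and in 12 control windows, AAACGCGC in 174 and 9, GCGCTCTA in 127 and 2, and AAGTGCGC in 133 and 8. These control windows were not matched in dinucleotides, and the 8-mers were not set beside shuffles. Replication and mitosis promoters differed from ribosomal protein promoters in what their summits held. The E2F core stood in 36 of 80 summit windows at replication and mitosis genes (45%) and in 3 of 69 at ribosomal protein genes (4.35%).

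GAGCGC at summits was weighed against the composition of the windows. It stood in 468 windows, while 100 shuffles that keep each window's dinucleotides gave 146 ± 10.8 and at most 174. This argues against base and dinucleotide composition as the only cause. The shuffled mean was above the 58 control windows with GAGCGC, so composition can account for part of the difference from controls. Promoter-proximal peaks with GAGCGC had a median signal value of 420 and those without it 168, a ratio of 2.50 (permutation p = 2e-05, the smallest that 100000 permutations can give). A hypothesis from these data is that the tagged protein, or a partner recovered with it, may prefer this sequence; a preference of open promoters for it in any ChIP was not tested, since no other factor's peaks were used here.

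One hypothesis was that the sequences divide the gene groups. The E2F core was more frequent at replication and mitosis than at ribosomal protein summits (odds ratio 15.6, 95% interval 4.88 to 49.7, two-sided Fisher p = 4.63e-09), and its 36 windows exceeded the 20 that shuffles of the same windows reached at most. The expectation that GAGCGC would be more frequent at ribosomal protein summits was not met: it stood in 15.9% of them and in 28.8% of replication and mitosis summits (odds ratio 0.481, 95% interval 0.217 to 1.06, Fisher p = 0.0787). At replication and mitosis genes its 23 windows exceeded the 11 of the highest shuffle. The E2F core was not limited to these genes, since it stood in 352 of all 2072 promoter-proximal windows, against at most 240 in shuffles.

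Another hypothesis was that summits away from promoters also carry GAGCGC. It stood in 248 of 1801 such windows (13.8%) and in 2.41% of windows 500 bp away (odds ratio 6.44, 95% interval 4.98 to 8.32, Fisher p = 2.42e-54). The windows 500 bp away were not matched in GC content, so this odds ratio cannot separate the sequence from composition. With tRNA genes left out GAGCGC stood in 14.5% of 1616 windows, more than in any of 100 shuffles that keep each window's dinucleotides. Those shuffles gave a mean of 106.5 ± 9.35 of the 1616 windows and at most 137, so composition accounts for part of the share. Among the 100 strongest peaks away from promoters, tRNA genes included, 38 had GAGCGC, and 8 of 190 windows 500 bp from them. Composition was not controlled for in this last comparison. Peaks away from promoters may thus share a sequence with those at promoters.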
